A study of Mus musculus with 2 samples.

How the data were processed

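Heart cells of old mice (20 to 22 months) were sorted by flow cytometry for the red fluorescent reporter mCherry of a p16 reporter strain, in which the reporter marks cells that use the p16 gene Cdkn2a. They were profiled by droplet single-cell RNA sequencing, which counts unique molecular identifiers (UMIs). The labels give 2 samples in 1 group and no comparison group. Per the submitters' processing notes, Cell Ranger 3.0.2 and the mouse build mm10 were used. The tool that normalized the values and the filters on cells and genes are not given in the sources used here.

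The deposited table holds 15247 genes in 1426 cells as the natural log of 1 plus UMIs per 10000 UMIs of the cell. This unit was read from the values: undoing the log gave a sum of 10000 in every cell. All 4459440 values above 0 were whole multiples of the lowest value of their cell within 1e-06, so UMI counts were recovered from the steps. Cell names carry 2 prefixes, called the libraries Heart1 and Heart2 here. The titles of the sample records differ by a 6-digit number that looks like a date and is not explained in the labels, so day of preparation and library cannot be separated. The cell names do not say which sample record each library is, nor whether each came from separate animals. So p-values measure only a spread between these libraries, pooled in large part over genes, which may be technical. Every column of cells was used (0 were left out). The lowest number of genes in a cell was 1140, the lowest UMI count 3164 and the highest mitochondrial share 9.97%, and each gene was present in at least 3 cells, so the table is a filtered one. No row is named for mCherry, the diphtheria toxin receptor or the FLP recombinase (0 rows), so the reporter RNA was not analysed here. Of the symbols, 15087 of 15247 were found in the gene name table. Gene positions are from the GENCODE annotation of GRCm38 (mm10).

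Cells were clustered with scanpy 1.11.5 and the Leiden method of igraph 0.11.9. Genes of the 14 fixed lists were kept out of clustering. The 2000 most variable genes, 30 principal components, 10 neighbours and a resolution of 1.0 were used, clusters were merged to broad classes at a correlation distance of 0.45, and the fibroblast-like and macrophage-like classes were clustered again (1500 genes, 20 components, resolution 0.5). These settings were chosen after seeing output. The kept setting was picked from 15 combinations because it set endothelial and T cells apart, and 4 merge distances from 0.25 to 0.4 were looked at before 0.45 was set. The sub-cluster resolution of 0.5 was kept over 1.0 with the Cdkn2a share of each sub-cluster in view. Values under all of these are in the closing part on processing. Classes were named from 21 fixed marker sets, by the set with most markers among the 50 genes with the highest fold against the cells of the other classes, with at least 3 markers detected in 25% of the cells. Taking the fold against other classes was also chosen after seeing output, since a plain comparison between clusters left fibroblast clusters led by markers of other types. Doublets were predicted with scrublet in each library and kept in the main values.

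The lists, the markers, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined. The rule names every detected member of the senescence core list and up to 3 members of each other list with the largest difference of at least 2-fold that were detected in 5% of cells. For cells with and without Cdkn2a it names the 10 list genes with the largest difference. Of the genes so named, 1 is not reported here. A count model was planned for whole recovered UMI counts, which these data gave. It was not run because the deposited unit is a log value, which the plan did not give as a reason, so the test used departed from the plan. In its place limma 3.58.1 (R 4.3.3) was used on log2(CPM + 5) of UMIs summed per library and class (CPM, UMIs scaled to the same total in each sum). Library was a block, with a mean-variance trend and Benjamini-Hochberg adjustment. Genes with a mean of 10 CPM or more were kept. Fold changes on this scale understate changes of low genes.

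The planned test asked for at least 50 cells of a class in each library. Only 1 class reached that, since the macrophage-like class had 38 cells in Heart1. The planned result is therefore a set of values without a test: genes at least 2-fold apart in both libraries. A limma fit with a lower minimum was added after the cells were counted. That minimum was first set to 40, which also left 1 class, and was then lowered to 30 so that both classes entered, so its p-values come from a threshold moved after the counts were known. It has 1 residual degree of freedom and 8.72 prior ones, which come from the spread of other genes. Its standard errors and p-values therefore rest mostly on that pooled spread. For Cdkn2a the planned minimum was 20 cells with a UMI in each library, which no class reached, so values are given for the library of each class that has enough such cells. Cells were thinned to 5000 UMIs there and to 3000 UMIs for shares of cells. Both depths were tried for the shares. A limma fit over macrophage-like cells of both libraries, unthinned, was added after seeing the data. It has 1 residual and 9.41 prior degrees of freedom.

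Limma fits of sub-clusters were also added. The fit of the 2 macrophage sub-clusters alone gave 99 genes higher and 238 lower in sub-cluster 1, but with infinite prior degrees of freedom and a smallest adjusted p of 1.3e-110, which is not usable. A second attempt, 1 fit with the fibroblast sub-clusters, gave 76 higher and 254 lower and made 32 false calls on simulated data. Both were dropped, and macrophage sub-clusters are given as values only. For the fibroblast sub-clusters the separate fit was kept, with 4 residual and 8.34 prior degrees of freedom. The joint fit called fewer genes, for example 255 higher and 229 lower in sub-cluster 6 against 340 and 375.

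Each fit was tested on simulated data with 200 genes changed. In the class fit (8680 genes), 64.0% of genes changed 2-fold and 99.0% of those changed 4-fold were recovered, with 11 false calls. In the fit of macrophage-like cells with and without Cdkn2a (7620 genes) these were 25.3% and 71.7%, with 8 false calls, and in the fibroblast sub-cluster fit (8544 genes) 51.0% and 94.0%, with 2 false calls.

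A list's median difference was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Shares have exact Clopper-Pearson 95% intervals, sums of UMIs exact Poisson ones, a ratio of CPM an exact binomial one given the summed UMIs, and a share of 0 the limit that 3 counts allow. These intervals cover counting error only. Alternatives tried were pseudocounts of 1 and 20 CPM, no filter on low genes, median ratio scaling, no replicate block, other clusterings, a stricter cell filter (2000 genes, 7.5% mitochondrial UMIs), thinning, removal of predicted doublets and leaving out each library.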

Results

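The data were single-cell profiles of mCherry-positive heart cells from old mice of a p16 reporter strain, 2 samples of 1 group. The sort asks which heart cells use the p16 gene late in life. Library Heart1 held 266 cells with 3304045 UMIs, a median of 11350 UMIs per cell (range 3223 to 57406) and a median of 3396 genes. Library Heart2 held 1160 cells with 10632723 UMIs, a median of 8886 UMIs (range 3164 to 79999) and 3079 genes. The median mitochondrial share was 3.64% in Heart1 and 5.22% in Heart2. No sample of unsorted or mCherry-negative cells was used here, so all shares are shares of sorted cells and are set by the gate.

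Most sorted cells were fibroblast-like or macrophage-like. Fibroblast-like cells, led by the collagen genes Col3a1 and Col1a2 and by Lum and Dcn, made up 78.2% of Heart1 (208 of 266 cells, interval 72.7 to 83.0%) and 81.0% of Heart2 (940 of 1160, 78.7 to 83.3%). Macrophage-like cells, led by Lyz2 and the complement genes C1qa and C1qb, made up 14.3% (38 cells, 10.3 to 19.1%) and 18.1% (210 cells, 15.9 to 20.4%). Vascular endothelial cell-like cells, with Cldn5 and Cdh5, were 2.26% of Heart1 (6 cells) and 0.776% of Heart2 (9 cells). T cell-like cells were 3.38% (9 cells, of which 7 were predicted doublets) and 0.0862% (1 cell). B cell-like cells were 1.88% of Heart1 (5 cells) and no cell of Heart2 was named so. Under a merge distance of 0.25, 6 classes were formed in place of 5 and the fibroblast-like class of Heart1 held 173 cells.

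Cdkn2a RNA was frequent in the macrophage-like cells of both libraries and in the fibroblast-like cells of Heart1, and rare in the fibroblast-like cells of Heart2. Cdkn2a encodes the cell cycle inhibitor p16 and, from another first exon, p19Arf. It lies on chromosome 4 (GRCm38, 89274471 to 89294653, minus strand, ENSMUSG00000044303.6), and its 2 coding transcripts share the last exon (89274541 to 89274774), so 3' UMIs do not tell p16 from p19Arf. Among fibroblast-like cells, 35.6% of Heart1 (74 of 208, 29.1 to 42.5%) and 0.745% of Heart2 (7 of 940, 0.30 to 1.53%) had a Cdkn2a UMI. Their summed level was 83.1 CPM (72.7 to 94.7) and 2.13 CPM (1.26 to 3.36). Among macrophage-like cells the shares were 42.1% (16 of 38, 26.3 to 59.2%) and 27.1% (57 of 210, 21.3 to 33.7%), and the levels 116 CPM (83.3 to 157.5) and 96.2 CPM (83.4 to 110.5). Of endothelial-like cells 3 of 6 and 2 of 9 had a Cdkn2a UMI, of B cell-like cells 3 of 5.

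Thinned to 3000 UMIs per cell, which left out no cell, the Cdkn2a shares were 16.4% and 0.319% of fibroblast-like and 18.4% and 15.7% of macrophage-like cells. Median depths of fibroblast-like cells were 11860 UMIs in Heart1 and 8771 in Heart2, and of macrophage-like cells 8005 and 9642. As a rough measure of RNA from other cells, the fibroblast gene Dcn had a UMI in 13.2% and 22.9% of macrophage-like cells and the macrophage gene Lyz2 in 7.21% and 7.34% of fibroblast-like cells. Both are far more abundant in their own class than Cdkn2a. The Dcn UMIs numbered 5 in 5 macrophage-like cells of Heart1 and 382 in 48 of Heart2, and Dcn was among the 10 leading genes of macrophage sub-cluster 2. The Heart2 share of Dcn is therefore not a measure of free RNA alone.

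Each of the 6 fibroblast sub-clusters had a higher Cdkn2a share in Heart1 than in Heart2. In sub-cluster 6 it was 61.1% (33 of 54, 46.9 to 74.1%) against 9.38% (3 of 32, 1.98 to 25.02%), in sub-cluster 4 45.3% (29 of 64, 32.8 to 58.3%) against 4.17% (2 of 48, 0.509 to 14.3%), and in sub-cluster 1 12.5% (2 of 16) against 0.308% (1 of 325). Sub-clusters 4 and 6 held 30.8% and 26.0% of the fibroblast-like cells of Heart1, and 5.11% and 3.40% of those of Heart2. In macrophage sub-cluster 1, 4 of 16 cells of Heart1 and 14 of 78 of Heart2 had a Cdkn2a UMI, and in sub-cluster 3 11 of 20 and 17 of 42, with overlapping intervals. Macrophage sub-cluster 2 held 2 cells of Heart1 and 90 of Heart2.

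**Figure D1:**
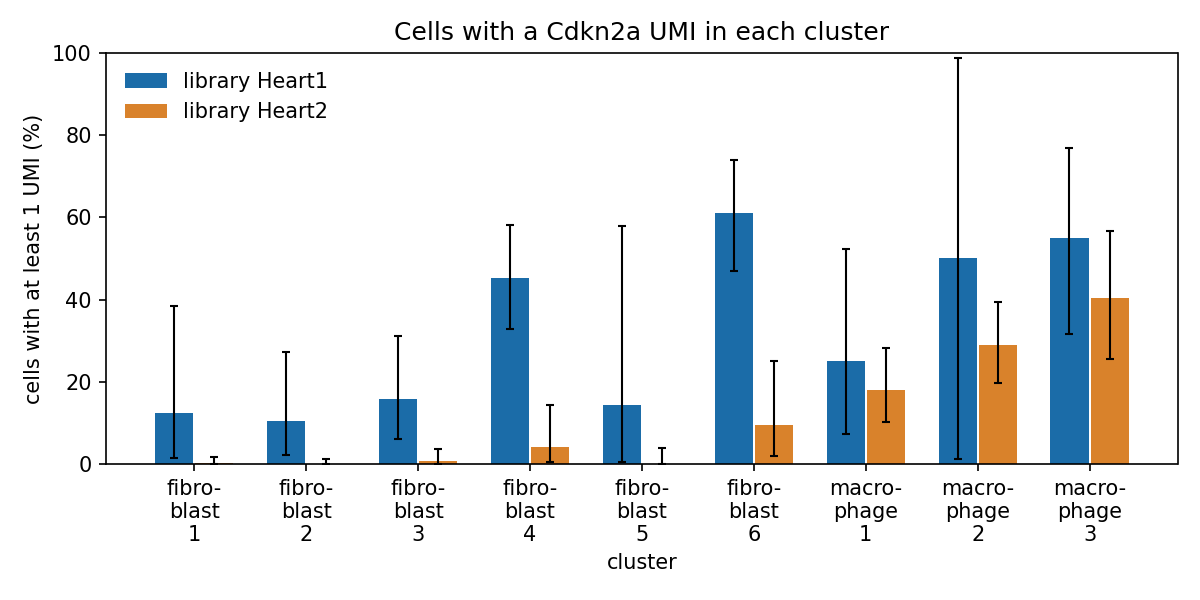
Share of cells with at least 1 Cdkn2a UMI (percent, vertical axis) in each fibroblast and macrophage sub-cluster of libraries Heart1 (blue) and Heart2 (orange), with exact 95% intervals of counting error. In fibroblast sub-cluster 6 the share was 61.1% in Heart1 and 9.38% in Heart2.

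In fibroblast-like cells Cdkn1a and Cdkn2b also had higher shares in Heart1, by smaller factors than Cdkn2a. The intervals of their shares in macrophage-like cells overlapped between libraries, but those of the summed Cdkn1a level did not. Cdkn1a, which encodes the p53-induced inhibitor p21 (chromosome 17, 29090976 to 29100727), had a UMI in 49.0% (42.1 to 56.0%) and 29.3% (26.4 to 32.3%) of fibroblast-like cells and in 19 of 38 and 37.1% of macrophage-like cells. Cdkn2b, the p15 gene beside Cdkn2a (chromosome 4, 89306299 to 89311039), had a UMI in 31.3% (25.02 to 38.02%) and 6.06% (4.63 to 7.79%) of fibroblast-like cells and in 15.8% and 9.52% of macrophage-like cells. Thinned to 3000 UMIs, the fibroblast-like shares were 26.9% and 16.7% for Cdkn1a and 10.6% and 2.02% for Cdkn2b, and the macrophage-like shares 39.5% and 21.9% for Cdkn1a and 0 of 38 and 2 of 210 cells for Cdkn2b. The summed Cdkn1a level of macrophage-like cells was 305.7 CPM (250.8 to 369.1) in Heart1 and 150.4 CPM (134.2 to 167.9) in Heart2. In fibroblast-like cells it was 266.2 CPM (247.2 to 286.2) and 152.0 CPM (143.8 to 160.6). UMIs of the proliferation genes Mki67 and Top2a were found in few cells. At this depth that bounds the share of cells with a UMI, not the share that use the genes. Some other genes of the proliferation list, such as Pcna and Stmn1, were found in more cells. Mki67 had a UMI in 1 of 208 and 0 of 940 fibroblast-like cells, the latter allowing a share of cells with a UMI of up to 0.319% (3 counts; exact upper bound 0.392%), and in 1 of 38 and 6 of 210 macrophage-like cells. Top2a, a mitotic topoisomerase gene, had a UMI in 0 of 208 and 1 of 940 fibroblast-like and in 1 of 38 and 9 of 210 macrophage-like cells.

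**Figure D2:**
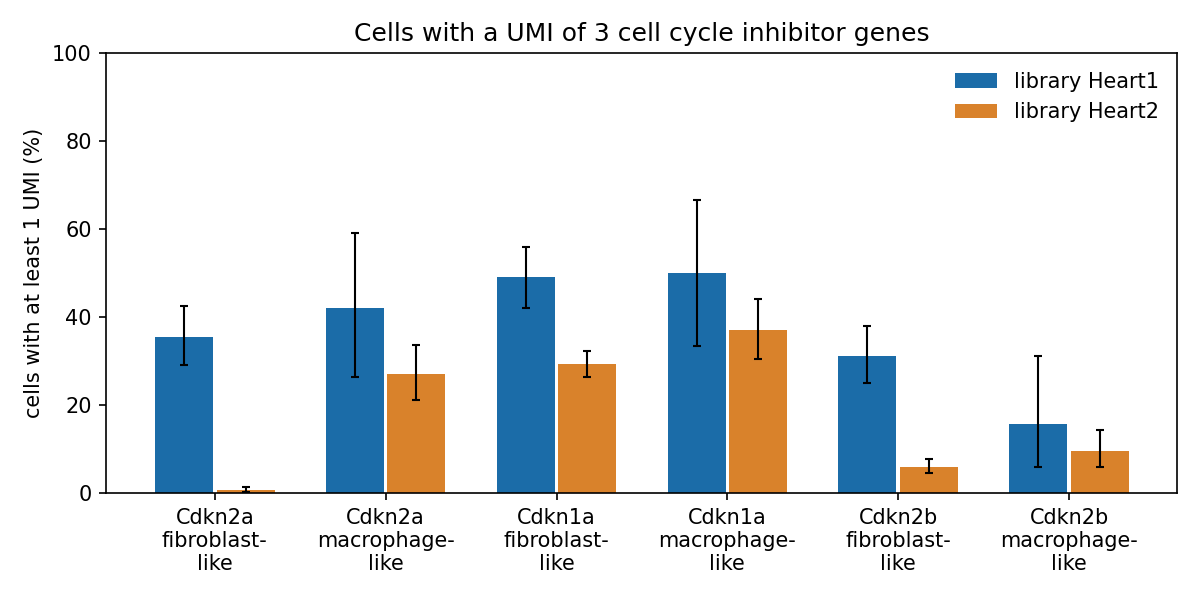
Share of cells with at least 1 UMI of Cdkn2a, Cdkn1a or Cdkn2b (percent, vertical axis) in fibroblast-like and macrophage-like cells of libraries Heart1 (blue) and Heart2 (orange), with exact 95% intervals of counting error. The Cdkn2a share of fibroblast-like cells was 35.6% in Heart1 and 0.745% in Heart2.

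Fibroblast-like and macrophage-like cells carried different secretory genes. Most genes of the matrix list were higher in fibroblast-like cells, and most of the antigen presentation, lysosome and scavenger receptor lists in macrophage-like cells. The secretory list was divided between the classes. Of 8797 genes, 1302 were at least 2-fold higher in fibroblast-like and 950 in macrophage-like cells in both libraries. The median gene differed by 0.16 (log2), and by 0.078 with median ratio scaling, so small differences are relative to that shift. The added limma fit, for which the minimum number of cells was lowered after the cells were counted, called 2133 genes higher and 1409 lower in fibroblast-like cells, and without the library block 1732 and 1211. Classes come from clustering these cells, so only genes of the lists, which were kept out of clustering, are described. Values below are log2 differences, fibroblast-like minus macrophage-like, with the limma standard error. That error is pooled mostly over genes (8.72 prior degrees of freedom against 1 residual), so it can understate the gap between libraries for a single gene.

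Of 20 matrix genes, 19 were at least 2-fold higher in fibroblast-like cells in both libraries and 0 in macrophage-like cells (limma 19 higher and 1 lower, and the same numbers adjusted over the list alone). Examples were Mgp, an inhibitor of calcification (8.41 ± 0.41), Sparc, a collagen-binding glycoprotein (8.17 ± 0.48), and the proteoglycan gene Bgn (7.39 ± 0.23). Of 38 secretory genes, 13 were higher in fibroblast-like and 17 in macrophage-like cells, and 8 were neither (limma 15 and 20, and 15 and 20 adjusted over the list alone). Igfbp7 (9.09 ± 0.45) and Igfbp6 (6.83 ± 0.37), both binding proteins, led one side and the chemokine gene Ccl6 (-7.72 ± 0.24) the other. Chemokine genes went both ways: Cxcl12 (3.35 ± 0.35) and Cxcl1 (2.11 ± 0.52), chosen after their values were seen, were higher in fibroblast-like cells.

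Of 9 antigen presentation genes, 8 were higher in macrophage-like cells and 1 neither (limma 0 higher and 8 lower, and 8 lower adjusted over the list alone), with Cd74, the invariant chain (-8.95 ± 0.38), H2-Aa (-8.49 ± 0.32) and H2-Eb1 (-8.16 ± 0.32). Of 23 lysosome genes, 14 were higher in macrophage-like cells, 1 in fibroblast-like cells and 8 neither (limma 2 higher and 18 lower, and 2 and 18 adjusted over the list alone), among them the proteases Ctss (-8.38 ± 0.21) and Ctsc (-6.74 ± 0.28) and the mannosidase gene Man2b1 (-3.54 ± 0.21). The protease gene Ctsl (1.57 ± 0.22) and the scavenger list gene Axl (1.83 ± 0.22), chosen after their values were seen, were higher in fibroblast-like cells. Of 8 scavenger receptor genes, 6 were higher in macrophage-like cells (limma 1 higher and 6 lower, and 1 and 7 adjusted over the list alone), such as Stab1 (-6.88 ± 0.30), the folate receptor gene Folr2 (-6.87 ± 0.40) and Cd163, which takes up haemoglobin (-5.99 ± 0.27). Of 13 lipid genes, 6 were higher in macrophage-like and 1 in fibroblast-like cells (limma 2 higher and 8 lower, and 2 and 9 adjusted over the list alone), with Trem2 (-6.45 ± 0.27), the fatty acid transporter gene Cd36 (-5.68 ± 0.27) and Lgals3 (-4.76 ± 0.56). Lgals3 was at 3241 CPM in macrophage-like cells of Heart1 and 493 CPM in those of Heart2.

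Of 13 core genes, 2 were higher in fibroblast-like cells, 1 in macrophage-like cells and 10 neither (limma 2 higher and 3 lower, and 2 and 3 adjusted over the list alone). The inhibitor genes Cdkn1c (2.59 ± 0.31) and Cdkn2c (1.21 ± 0.23) were higher in fibroblast-like cells and the chromatin gene Hmgb2 (-1.28 ± 0.21) in macrophage-like cells. Rb1 differed by -1.12 ± 0.26 and Cdkn2a by -2.14 ± 0.59 (limma adjusted p = 0.0151). The Cdkn2a value rests on Heart2, with -0.46 in Heart1 and -3.83 in Heart2, a gap that the pooled standard error understates. Differences were 0.56 for Cdkn1b, 0.55 for Trp53, 0.40 for Hmgb1, 0.24 for Cdkn2d, 0.13 for Cdkn2b, -0.09 for Cdkn1a, -0.41 for the senescence-associated galactosidase gene Glb1 and -0.75 for the lamin gene Lmnb1. Their limma adjusted p-values lay between 0.0889 for Trp53 and 0.804 for Cdkn2b. The median of the core list was 0.13 over the mean of the libraries, -0.063 in Heart1 and 0.016 in Heart2, so its sign is not settled.

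Of 13 p53 target genes, 1 was higher in each class and 11 neither (limma 1 higher and 4 lower, and 1 and 4 adjusted over the list alone). Phlda3 was higher in fibroblast-like cells (2.88 ± 0.21) and the stress gene Sesn1 in macrophage-like cells (-1.51 ± 0.26). Gdf15 differed by -0.61 in Heart1 and -2.37 in Heart2. Of 11 proliferation genes, 5 were higher in macrophage-like cells and 6 neither (limma 0 higher and 5 lower, and 1 and 6 adjusted over the list alone), among them Stmn1, a microtubule regulator (-3.13 ± 0.25), and the replication gene Mcm3 (-1.44 ± 0.27). Cenpa was -0.17 in Heart1 and -2.37 in Heart2 (limma adjusted p = 0.0560). Of 16 interferon genes, 3 were higher in macrophage-like cells and 13 neither (limma 0 higher and 8 lower, and 9 lower adjusted over the list alone), including Oas1a (-2.28 ± 0.37) and Zbp1 (-2.03 ± 0.33). Ifi44 had no UMI in fibroblast-like cells and 36.8 and 61.8 CPM in macrophage-like cells.

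Of 10 BCL2 family genes, 4 were higher in macrophage-like cells and 6 neither (limma 0 higher and 7 lower, and 7 lower adjusted over the list alone). Bcl2a1b, a survival gene whose near-identical copies can share reads, differed by -5.61 ± 0.28 and the death-promoting gene Bcl2l11 by -1.81 ± 0.30. Bcl2a1d had no UMI in fibroblast-like cells and 23.9 CPM in macrophage-like cells of Heart2. Of 11 iron and oxidative stress genes, 4 were higher in macrophage-like cells and 7 neither (limma 0 higher and 4 lower, and 4 lower adjusted over the list alone), with the iron exporter gene Slc40a1 (-2.73 ± 0.24), the haem oxygenase gene Hmox1 (-2.52 ± 0.26) and the ferritin gene Ftl1 (-1.50 ± 0.11). Of 18 dissociation stress genes, 2 were higher in fibroblast-like cells, 1 in macrophage-like cells and 15 neither (limma 6 higher and 2 lower, and 6 and 2 adjusted over the list alone), with Egr1 (2.34 ± 0.20), Nr4a1 (2.28 ± 0.29) and Atf3 (-1.73 ± 0.23). Their levels differed between libraries in both classes: Fos was at 876 CPM in fibroblast-like cells of Heart1 and 145 in those of Heart2, and at 527 and 133 in macrophage-like cells. Of 8 mitochondrial transcripts, 0 were 2-fold apart (limma 0 higher and 1 lower, and 1 lower adjusted over the list alone).

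**Figure D3:**
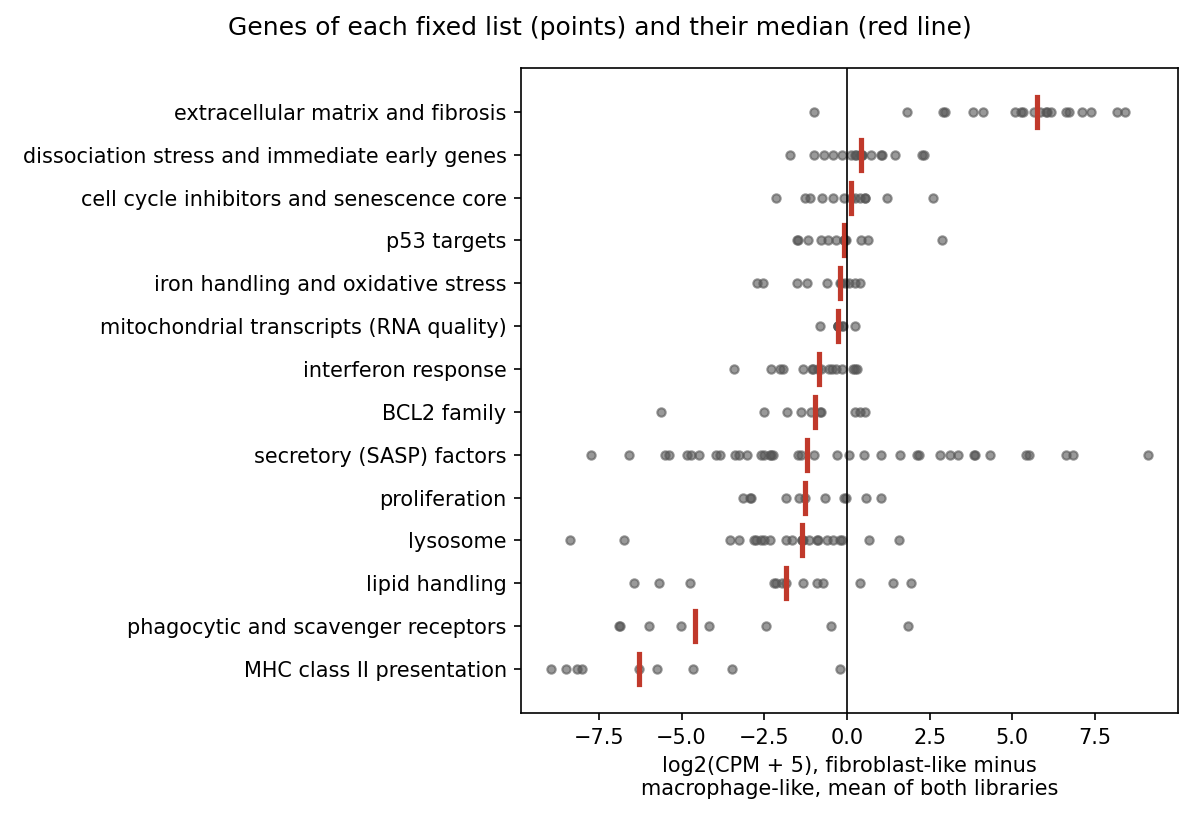
Difference between fibroblast-like and macrophage-like cells (horizontal axis, log2(CPM + 5), mean of both libraries) for the genes of each fixed list (points) and the median of the list (red line). The median of the matrix list was 5.74 and that of the antigen presentation list -6.28.

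Within a class, cells with a Cdkn2a UMI were set beside cells without, which asks what goes with the gene behind the reporter among sorted cells. In fibroblast-like cells of Heart1 (47 with and 155 without a UMI after thinning to 5000 UMIs, 6 shallower cells left out), 23 of 164 list genes were at least 2-fold higher in the cells with a UMI and 10 lower. Of all 8486 genes compared, 551 were higher and 479 lower, so lower genes were about as frequent among all genes as in the lists. The lower list genes numbered 3 unthinned, 3 matched on genes detected and 6 within sub-clusters. Among the core and p53 genes, higher ones were Cdkn2b (2.34, 34 UMIs against 19), the p53 regulator Mdm2 (2.10, 22 against 14) and Cdkn1a (1.88, 139 against 122), while the inhibitor gene Cdkn1c was lower (-1.19, 10 against 80, chosen after its value was seen). With status and values taken from unthinned cells, Mdm2 was 0.90, Cdkn1a 0.68 and Cdkn2b 1.76. The early response genes Ier3 (2.39) and Junb (2.19) were also higher. With the sub-cluster mix evened out, Ier3 was 1.561, Junb 1.542 and Cdkn2b 1.685, all smaller, while Mdm2 (2.537) and Cdkn1a (2.25) were larger. Spp1, a matrix cytokine gene, was higher by 3.42, with its 138 UMIs in 6 of the 47 cells. Igfbp5 was lower (-2.39), and Hmox1 had 3 UMIs against 49, a CPM ratio of 0.202 (0.0403 to 0.626), but unthinned they were -0.86 and -0.64, under 2-fold. Igfbp3 had no UMI in the cells with Cdkn2a and 36 UMIs in 10 of the 155 cells without. It was at least 3.64-fold lower against a floor of 3 UMIs, a bound that covers counting of UMIs only. Unthinned it was -1.74, and both values rest on few cells. The median of the core list was -0.064, at the percentile 27.03 of random lists. The median of the p53 target list was 0.66, above 99.9% of random lists, and that of the dissociation stress list 1.15. These are values of 1 library with no test.

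In macrophage-like cells of Heart2 (39 with and 153 without, 18 shallower cells left out), 17 of 175 list genes were at least 2-fold higher and 23 lower, many on few UMIs. Of all 7716 genes compared, 394 were higher and 387 lower. Unthinned, 10 list genes were higher, and with a pseudocount of 20 CPM 10 list genes were higher and 13 lower. Stmn1 (2.29) was higher and Junb (-1.94) lower. The mitotic genes Birc5, with 12 UMIs against 3 (CPM ratio 15.7, 4.24 to 86.7), and Ccnb2, with 6 against 2 (11.8, 2.11 to 119.3), had their UMIs in 2 of the 39 cells. The chemokine gene Cxcl2 had 1 UMI against 396 (0.00991, 0.00025 to 0.0555), the interferon gene Ifit3 1 against 33 (0.119, 0.0029 to 0.7104) and the cytokine gene Il1b 1 against 25 (0.157, 0.0038 to 0.959). For each of these genes the UMIs lay in 1 of the 39 cells with Cdkn2a and 10 of the 153 without. These ratios therefore rest on few cells. Egr1 had no UMI in the cells with Cdkn2a and 21 UMIs in 8 of the 153 cells without. It was at least 1.78-fold lower against a floor of 3 UMIs, which covers counting of UMIs only. Against cells matched on genes detected, unthinned, Ifit3 was -0.95, Il1b -0.022 and Egr1 -0.23, all under 2-fold. Igfbp7 (2.00, 7 UMIs against 4) and Mgp (1.99, 12 against 9), which are fibroblast genes in these data, were higher after thinning, but Igfbp7 was 0.88 against matched cells and Mgp 0.55 without predicted doublets. The median of the antigen presentation list was -1.23 and that of the proliferation list 1.53. Of the 13 proliferation genes, Mki67, Top2a, Ube2c, Cdk1, Birc5, Ccnb2, Mcm6 and Mcm7 had their UMIs in 2 of the 39 cells each. This median therefore rests on few cells.

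The limma fit over macrophage-like cells of both libraries (16 with and 22 without in Heart1, 57 and 153 in Heart2, unthinned), added after seeing the data, called 2 of 7776 genes higher and 9 lower, with 489 at an unadjusted p under 0.05. Of 9 antigen presentation genes 6 were lower (7 adjusted over the list alone), including Cd74 (-2.02 ± 0.10, limma adjusted p = 5.5e-06) and H2-Ab1 (-2.26 ± 0.13). Of 14 proliferation genes 1 was higher, Stmn1 (2.94 ± 0.30, limma adjusted p = 0.0021), and 7 adjusted over the list alone. Among these 7, Mki67 had a UMI in 1 of 38 macrophage-like cells of Heart1 and 6 of 210 of Heart2. Top2a had one in 1 of 38 and 9 of 210. The mitotic genes thus rest on few cells, which a fit of summed UMIs does not take into account. Without the library block the limma fit called 1 gene higher and 4 lower. Cells with a UMI were deeper, with a median of 9832 against 6800 UMIs in Heart1 and 11330 against 9285 in Heart2.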

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

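All tests of the Cdkn2a difference between libraries and the test of the macrophage sub-cluster mix were chosen only after the result was seen, while those on depth and doublets in macrophage-like cells were written before.

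Among 131 list genes measured in both comparisons of cells with and without a Cdkn2a UMI, 3 were at least 2-fold apart in opposite directions in fibroblast-like cells of Heart1 and macrophage-like cells of Heart2. Junb differed by 2.19 (log2) in fibroblast-like and -1.94 in macrophage-like cells. Egr1 differed by 1.41 and -2.70, the latter with no UMI in the macrophage-like cells with Cdkn2a, so it depends on the pseudocount. For Egr1 in macrophage-like cells the difference was -0.92 unthinned and -0.23 against matched cells, under 2-fold in both. The fatty acid binding protein gene Fabp5 differed by 1.04 and -1.13, the latter from 4 UMIs against 39, a CPM ratio of 0.402 with an interval that includes 1 (0.104 to 1.12). The difference was not tested, and the 2 classes come from different libraries.

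Cdkn2a UMIs were found in 35.6% of fibroblast-like cells of Heart1 and 0.745% of those of Heart2. The tables argue against the mix of sub-clusters as the whole source: with the share of each sub-cluster as in Heart1, 15.85% of the fibroblast-like cells of Heart2 would have a UMI, against an upper bound of 1.53%. A lower capture of the gene in all of Heart2 is argued against by the macrophage-like cells, where the Cdkn2a level of Heart2 was 0.829 times that of Heart1 (0.590 to 1.19), against 0.0256 times (0.0149 to 0.0414) in fibroblast-like cells. A gate that let in cells without reporter RNA in 1 library cannot be told apart from a difference between the sorted preparations, since 0 rows of the table are named for the reporter. The sample titles differ by a number that looks like a date, which cannot be told apart from the library, and no biological explanation was tested.

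In macrophage-like cells of Heart2 with a Cdkn2a UMI, the median of the antigen presentation list was -1.23. Against cells matched on the number of genes detected it was -0.972, which argues against depth as the whole source. Without the 2 predicted doublets it was -1.20, which argues against these doublets, though few were removed. With the sub-cluster mix evened out it was -1.05, and since resampled cells reach values above the bound set for this test, a difference in sub-cluster mix cannot be told apart from a difference within sub-clusters. No biological explanation was tested.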

How the results depend on the processing

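Clustering at the halved resolution and with list genes included was planned. The other clusterings, the limma fits, the evened sub-cluster mix and the second thinning depth were chosen only after the result was seen. So were pseudocounts in the comparison by Cdkn2a status. Removal of predicted doublets was also added then, apart from the doublet tests described here as written before. The remaining alternatives were planned. Of 366 values of the 34 main results under alternatives, 289 stayed and 77 moved. Of 563 values of 77 single genes and other values, 479 stayed and 84 moved. A value stayed within 1 SD of the libraries (class shares, list medians and genes between classes), within its exact 95% interval (shares of cells with a UMI), within 1.5 times (counts) or at 2-fold or more (genes by Cdkn2a status). No difference of at least 2-fold changed sign (0 values). Smaller ones did when a library was left out: the core list (-0.063 against 0.13) without Heart2, Cdkn1a and Cdkn2b (0.016 and -0.51) without Heart1 and Cdkn2d (-0.063) without Heart2. The planned count model and its alternatives were not run, a departure from the plan. With 1 library in each comparison by Cdkn2a status, none was left out there. Without the library as replicate block, the class fit called 1732 genes higher and 1211 lower, against 2133 and 1409. Where not stated, the cause was not tested. Depth limits shares of cells with a UMI, as the thinned values show, and so does the number of cells: 0 of 38 would allow 7.89% by the limit of 3 counts and 9.25% by the exact bound. With a pseudocount of 20 CPM, Cdkn2c (0.98), Rb1 (-0.78) and Mcm3 (-0.91) were under 2-fold between classes.

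The fibroblast-like share (mean of libraries 79.6%) was 85.3% under the stricter cell filter. Among the clusterings looked at, it was 82.3% with 15 neighbours and either 2000 genes at resolution 2.0 or 3000 genes at 1.0, 82.3% and 82.6% with 3000 genes and 40 components at resolutions 1.0 and 0.5, and 72.9% at merge distances of 0.25 and 0.3. At those distances the Cdkn2a share of fibroblast-like cells of Heart1 was 28.3%. Over all settings looked at it lay between 28.3% and 36.7% in Heart1 and between 0.641% and 1.15% in Heart2.

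Thinned to 3000 UMIs, the Cdkn2a share was 16.4% in fibroblast-like cells of Heart1 and 18.4% and 15.7% in macrophage-like cells of Heart1 and Heart2. The Cdkn1a share was 26.9% and 16.7% in fibroblast-like cells and 21.9% in macrophage-like cells of Heart2. At 5000 UMIs the Cdkn2a share was 21.8% in fibroblast-like cells of Heart1 and 19.3% in macrophage-like cells of Heart2, and the Cdkn1a share 32.7%, 21.0% and 29.2% in the same order. Fewer UMIs per cell lower these shares by construction. With the stricter filter the Cdkn1a share of macrophage-like cells of Heart2 was 44.1%.

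The mean over cells of the deposited values, which weights cells equally and shrinks differences of low genes, gave list medians of 0.063 (core), -0.097 (secretory), -0.088 (proliferation), -0.97 (lysosome), -2.15 (antigen presentation), -0.091 (interferon), -0.28 (lipid), -0.83 (scavenger), -0.23 (BCL2), 1.57 (matrix), 0.27 (dissociation stress) and -0.059 (iron). With a pseudocount of 1 CPM they were -7.77 (antigen presentation), -6.74 (scavenger), 7.52 (matrix) and 0.42 (dissociation stress), and with 20 CPM -4.56, -2.81, 4.05 and 0.39 in the same order and -0.88 (secretory). The stricter filter gave -0.74 (secretory), -5.61 (antigen presentation) and 0.58 (dissociation stress). At the halved resolution they were 0.22 (core), -0.91 (secretory) and 0.40 (dissociation stress), and with list genes included -5.80 (antigen presentation) and 0.40 (dissociation stress). Median ratio scaling gave 0.059 (core), 0.32 (dissociation stress) and -0.31 (iron), and removal of doublets 0.41 (dissociation stress).

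Leaving out each library gave medians from -0.063 to 0.016 (core), -0.85 to -0.51 (secretory), -0.33 to -0.20 (p53), -1.45 to -0.45 (proliferation), -2.17 to -0.86 (lipid), 0.50 to 0.50 (dissociation stress, 0.498 and 0.501) and -0.29 to -0.27 (iron).

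In the comparison by Cdkn2a status, lower list genes of fibroblast-like cells numbered 3 unthinned, 3 matched on genes detected, 6 with a pseudocount of 20 CPM and 6 within sub-clusters, against 10. Higher list genes of macrophage-like cells numbered 10 unthinned and 10 with 20 CPM, against 17, and lower ones 13 with 20 CPM, against 23. The limma fit called 53 higher and 60 lower with no low filter, where its prior degrees of freedom were infinite and the counts are not usable, and 1 and 4 with no replicate block, against 2 and 9. Fibroblast sub-cluster 6 had 556 higher and 318 lower with no low filter and 255 and 229 in the joint fit, against 340 and 375, and sub-cluster 4 had 160 and 154 with no replicate block and 194 and 171 in the joint fit, against 276 and 271.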

Other observations

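The limma fit of fibroblast sub-clusters, the values of macrophage sub-clusters and the split by library of the test of macrophage RNA were chosen only after results were seen, while the other tests of macrophage RNA and doublets in sub-cluster 6 were written before. Genes named here were chosen after their values were seen, and all are list genes, which were kept out of clustering. Sub-clusters were drawn on the same cells, so genes that go with the clustering genes differ by construction.

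Fibroblast sub-cluster 6, led by Wif1 and Coch, had more Cdkn2a (log2 2.67 ± 0.39 against the other 4 sub-clusters with at least 15 cells in each library, limma adjusted p = 0.00073) and Cdkn2b (2.38 ± 0.32, limma adjusted p = 0.00041). Of 18 dissociation stress genes 11 were higher and 0 lower (13 and 0 adjusted over the list alone), such as Zfp36 (3.17 ± 0.29) and Nr4a1 (2.84 ± 0.27). Of 20 matrix genes 3 were higher and 10 lower (3 and 13 adjusted over the list alone), with the basement membrane collagen gene Col4a1 at -2.12 ± 0.16. Sub-cluster 4, led by Thbs4 and Comp, had more Spp1 (6.58 ± 0.34), the matricellular gene Postn (4.77 ± 0.32), the fibronectin gene Fn1 (3.94 ± 0.37) and Cdkn1a (1.91 ± 0.32, limma adjusted p = 0.0026), and less of the lipase gene Lpl (-2.87 ± 0.14). There 8 of 20 matrix genes were higher and 0 lower (10 and 1 adjusted over the list alone), and 3 of 11 p53 targets were higher (4 adjusted over the list alone). In sub-cluster 4 also 4 of 8 mitochondrial transcripts were lower (6 adjusted over the list alone), and 2 of 18 dissociation stress genes were higher (2 adjusted over the list alone) with a list median of 0.42.

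Macrophage sub-cluster 3 had more Cdkn1a than sub-cluster 1 in both libraries (log2 2.38 in Heart1 and 2.22 in Heart2) and more Stmn1 (3.94 and 3.84), and less H2-Eb1 (-2.75 and -2.15). Gdf15 had no UMI in sub-cluster 1 and 40.6 and 146.0 CPM in sub-cluster 3. In both libraries 13 of 30 secretory genes and 7 of 14 proliferation genes were at least 2-fold higher, and 7 of 10 antigen presentation genes lower. Of all 7696 genes compared, 241 were higher and 100 lower. The proliferation genes Mki67 and Top2a had a UMI in 1 of 38 macrophage-like cells of Heart1, so their values in that library rest on 1 cell each. The dissociation stress list moved with the secretory and proliferation lists, with 6 of 18 genes higher and 0 lower. Its summed level was 12290 against 4799 CPM in Heart1 and 6312 against 3587 CPM in Heart2. These are values with no test. At least 3 of 8 mitotic genes, a rule added after seeing the data, were found in 1 of 38 and 5 of 210 macrophage-like cells, and 1 and 3 of these cells had a Cdkn2a UMI. The 5 cells of Heart2 had a median of 18560 UMIs, against 9642 over all macrophage-like cells of Heart2. Deeper cells are likelier to show both mitotic genes and Cdkn2a, so no link between them is drawn from these few cells.

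Of 5 antigen presentation genes 4 were higher in fibroblast sub-cluster 6 and 1 lower (4 and 1 adjusted over the list alone), with Cd74 at 4.65 ± 0.39 and H2-Ab1 at 4.20 ± 0.36 (limma), and Cd74 had a UMI in 10 of 54 cells of Heart1 and 3 of 32 of Heart2. In Heart1, RNA from macrophages stays a possible explanation: the macrophage genes C1qa, C1qb, C1qc, Lyz2 and Ctss reached 0.624 (median) of the level that a macrophage share giving the measured H2-Aa would bring, though their sum was 323 CPM (upper bound 369) against 682 needed. In Heart2 these genes reached 0.0290 of the needed level, with a sum of 17.1 CPM (upper bound 39.9) against 641, which argues against macrophage RNA in that library, where 4 cells had an H2-Aa UMI. Removing the 1 predicted doublet of the sub-cluster left Cd74 at 1.007 times its level, which argues against that doublet alone. No biological explanation was tested.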
